A study of Caenorhabditis elegans with 8 samples.

How the data were processed

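Whole Caenorhabditis elegans of the strain named by the labels for the cuticle collagen gene col-121 were picked at the late L4 larval stage and kept for 24 hours with the insect repellent DEET or with its solvent DMSO alone. Per the labels, each sample held 1000 worms, the control dose was 0.1% DMSO, and DEET was dissolved in DMSO at 0.1 M. The labels do not say whether 0.1 M was the stock or the final concentration, so no exposure level is stated here. There were 4 DEET and 4 DMSO samples, described in the labels as independent biological repeats. Each label also carries a pair number from 1 to 4, marked as a batch, that joins 1 DEET and 1 DMSO sample.

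Per the labels' protocols, RNA was extracted with a column kit, polyadenylated RNA was made into libraries with the Kapa mRNA HyperPrep kit, and paired reads of 38 nucleotides were taken on an Illumina NextSeq. Per the submitters' processing notes, Salmon and DESeq2 were used and the genome build was WBcel235; versions and settings are not given in the sources used here. The deposited count table held whole-number counts per gene, not normalized, for 46244 gene identifiers and 8 libraries. The deposited TPM table held TPM values, transcript abundances scaled to a fixed total per library, for the same genes and libraries. A quantifier of this kind shares reads among similar transcripts by a model, so counts of close paralogs and of overlapping genes can carry part of each other's reads, and strand use in the counting is not given in the sources used here. Read pairs carry no molecular identifiers.

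The identifiers were sequence names with a low line in place of the point. Of them, 46177 were matched by sequence name to 1 gene each of the Ensembl annotation of the same build, 5 took only a symbol from the RefSeq gene table, 3 shared a sequence name with more than 1 annotated gene, and 59 were not matched. Coordinates are 1-based and come from that annotation.

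Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 on the deposited counts, with TMM scaling, the default expression filter by group, robust dispersion estimation and Benjamini-Hochberg adjustment. The filter left 15496 genes. Tests were two-sided with a threshold of 0.05 on the adjusted p. The main fit held the treatment alone, because no source used here says that the authors modelled the pair. A fit with the pair number as a block was set beside it. Unless another tool is named, every adjusted p for a gene below comes from this edgeR test, and log2 fold changes are DEET over DMSO. The SE given with an edgeR log2 fold change is its size divided by the square root of the test's F statistic. It therefore restates the p of the test and is not a separate estimate of precision.

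The pair numbers were checked against the data. The deviation of each library from its group's mean log2 CPM was correlated across genes between the groups, and the correlation within a pair was 0.43 for pair 1, 0.71 for pair 2, 0.56 for pair 3 and 0.90 for pair 4. All 8 libraries correlated best with the library of their own number. The numbers therefore pair the samples, as the labels state, and blocked values are given where they change a call. Within groups, a chi-square per gene between libraries was 14.4 at its lowest, far above sampling noise, so no library was counted as a repeat of another.

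A set of 35 gene lists was tested with camera from limma 3.58.1, with an inter-gene correlation preset at 0.01, and again with the correlation estimated for each list. With 8 libraries the estimated form rests on few residual degrees of freedom, and it passed no list in any fit. A list that does not pass it is therefore not shown to be unchanged. Lists needed at least 3 tested members. They covered detoxification enzymes, stress and immune genes, the cuticle, germline, sperm, oocyte and embryonic genes, basic metabolism, signalling, markers of neurons, muscle, pharynx and intestine, and X-linked genes. The fry test of limma, which asks whether a list's genes move at all, was run as an alternative. Ratios per pair are differences of log2 CPM with a prior count of 2. Values of a list per pair are means over its members.

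The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named up to 5 genes per direction past the threshold without the block, with a mean of at least 50 counts and the same direction in 4 pairs, and the leading members of each list with called genes. No gene met it, since none passed without the block. All genes named below were therefore chosen after their values were seen, as genes called with the block or by DESeq2, or as leading members of a list, apart from col-121, which names the strain. Apart from DESeq2 with the block and the estimated correlation with the block, the fits that vary a choice while keeping the block were also chosen after seeing the data, as were those that leave out pair 4 or ribosomal RNA genes.

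The alternatives were the pair block, DESeq2 size factors, upper-quartile factors, no filter, a mean of at least 50 counts, each library left out in turn, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 1 and without that filter, DESeq2 1.42.0 with and without the block, and stricter thresholds. The procedure was tested on simulated counts built from the 4 pairs, with 200 changed genes among 15348 that passed the filter. Without the block it recovered 0% of genes changed 1.25-fold, 14% of those changed 1.5-fold, 40% at 2-fold and 78% at 4-fold, and called no unchanged gene. With the block it recovered 72%, 78%, 90% and 100%, and called 11 of 15148 unchanged genes. The simulated changes were equal in all 4 pairs, the noise was that of the blocked fit, and genes with few expected counts were left unchanged. With 200 changed genes the adjusted threshold is also easier to pass than where few genes change. These rates therefore describe the simulation and are not the share of changes found in the data. Figures were drawn with matplotlib.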

Results

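The data were gene counts from polyadenylated RNA of whole worms, 4 samples with DEET and 4 with DMSO, taken 24 hours after the exposure began. The libraries held 44437681 to 50295321 counts each. Ribosomal RNA took 3.91% to 10.9% of the counts in the DMSO libraries and 5.99% to 12.07% in the DEET libraries, with the highest share of each group in pair 4. The series asks how DEET changes gene expression, with germline dysfunction named in its title.

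The pairs differed more than the treatments did. The first principal component of log2 CPM held 68.2% of the variance and set pair 4 (scores of -67.7 for DMSO and -61.1 for DEET) against pair 2 (36.5 and 45.5) and pair 3 (31.1 and 19.5), with pair 1 between them. DEET and DMSO were parted by the fourth component, with 5.18% of the variance. On it the DMSO libraries scored 8.62 to 15.4 and the DEET libraries -13.9 to -8.41.

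**Figure D1:**
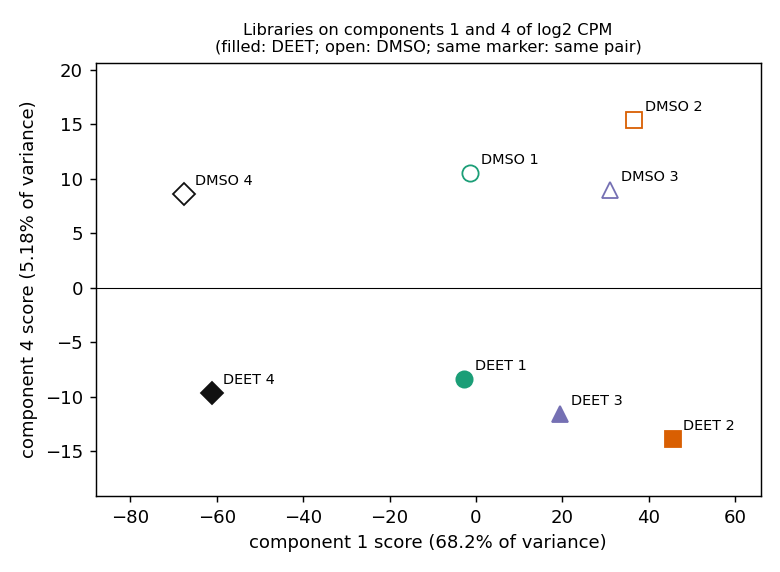
Scores of the 8 libraries on components 1 and 4 of log2 CPM over 15496 genes, with filled markers for DEET, open markers for DMSO and 1 marker shape per pair. The axis holding 68.2% of the variance separates the pairs, and the axis holding 5.18% separates the treatments.

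Worms exposed to DEET carried more transcript of a small set of genes led by cytochrome P450 enzymes, which oxidise foreign compounds. With the pair as a block, 13 genes were higher in DEET and 0 were lower, and all 13 were higher in 4 of 4 pairs. Besides the P450 genes cyp-14A2, cyp-14A3 and cyp-34A10 they comprised the UDP-glucuronosyltransferases ugt-25 and ugt-33, which conjugate sugars to such compounds, the short-chain dehydrogenase dhs-23, the alcohol dehydrogenase gene sodh-2, and R02C2.7, H25K10.4, R05D8.9, F38C2.1, F25D1.5 and E02C12.10. The fitted rises ran from 2.59-fold for ugt-33 to 99.5-fold for cyp-14A3, and the size of the largest depended on pair 4: the blocked log2 fold change of cyp-14A3 was 5.91 without pair 4 and 7.16 without pair 1, against 6.64 with all pairs.

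Without the block, the spread between pairs entered the error and edgeR called 0 genes, with 45 at an unadjusted p under 0.05 and a smallest adjusted p of 0.056. DESeq2 called 10 genes without the block, all higher, and 20 with it, 18 higher and 2 lower. The blocked edgeR fit had 526 genes at an unadjusted p under 0.05. Both this count and the 45 without the block lie below the 1 in 20 of 15496 tested genes that chance alone would give. Neither is therefore a sign of a wider response. The blocked edgeR fit called 12 genes higher and 1 lower without pair 1, 12 higher and 4 lower without pair 4, and 22 higher and 8 lower without a filter. Of the 13 genes, 6 passed with any single pair left out: cyp-34A10, cyp-14A3, R02C2.7, H25K10.4, R05D8.9 and sodh-2. Among these, only R02C2.7 and H25K10.4 also passed with the block on both log2(TPM + 1) and log2(TPM + 0.1). On log2(TPM + 1) cyp-14A3 was lost, on log2(TPM + 0.1) sodh-2 was lost, and cyp-34A10 and R05D8.9 passed on neither. The unblocked count was 1 without the DMSO library of pair 4, 3 without the DEET library of pair 4 and 4 without both.

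Among the 13 genes, R02C2.7 (chromosome V, 241326 to 242618) had the smallest standard error of its log2 fold change. Its level went from 5.59 ± 1.78 TPM in DMSO to 31.4 ± 7.48 TPM in DEET (SD, n = 4). Its log2 fold change was 2.49 ± 0.12 (SE) with an adjusted p of 3.0e-06 in the blocked fit and 0.064 without the block.

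Both cyp-14A genes lie on chromosome X, a few kilobases apart. Transcript of cyp-14A3 (13271837 to 13274202) was almost undetected in DMSO, with 2 to 6 counts per library, against 135 to 763 counts in DEET. Its log2 fold change was 6.64 ± 0.24 (SE), with adjusted p values of 2.1e-07 with the block and 0.056 without. Its neighbour cyp-14A2 (13267562 to 13269686) went from 1.42 ± 0.31 to 9.02 ± 4.61 TPM (SD, n = 4), a blocked log2 fold change of 2.61 ± 0.22 with an adjusted p of 0.0096, against 0.201 without the block. That call was lost without pair 1 or pair 2, with a highest adjusted p of 0.392. The log2 fold changes there were 2.74 ± 0.32 and 2.63 ± 0.29 (SE), no smaller than with all pairs. How the reads divide between these neighbours was not tested.

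On chromosome V, cyp-34A10 (3970702 to 3972991) had 1 to 12 counts per DMSO library and 44 to 773 per DEET library. Its blocked log2 fold change was 5.83 ± 0.20 (SE) with an adjusted p of 2.1e-07, against 0.867 without the block. It stands beside the related gene cyp-34A9, and its counts are uncertain as to the copy they came from.

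H25K10.4 (chromosome IV, 16226047 to 16227122) stood at 0.26 ± 0.13 TPM in DMSO and 9.19 ± 4.96 TPM in DEET (SD, n = 4). It had 1 to 4 counts per DMSO library and 44 to 155 per DEET library. Its blocked log2 fold change was 5.07 ± 0.26 (SE), with adjusted p values of 3.7e-06 with the block and 0.056 without. About 20 kilobases away, F38C2.1 (16247431 to 16251790) had 0 to 6 counts per DMSO library and 11 to 171 per DEET library, and its blocked log2 fold change of 4.22 ± 0.43 (SE) went to 3.37 ± 0.65 and lost its call without pair 4 (adjusted p = 0.268). R05D8.9 and sodh-2 had blocked log2 fold changes of 2.59 ± 0.20 and 2.12 ± 0.19 (SE), with adjusted p values of 2.9e-04 and 0.0010. sodh-2 overlaps adh-1 on the opposite strand, a gene with far more counts.

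Each remaining call was lost without at least 1 pair. dhs-23, at 1.19 ± 1.40 TPM in DMSO and 16.54 ± 15.8 TPM in DEET (SD, n = 4), had a blocked log2 fold change of 3.83 ± 0.27 (SE) and lost its call without pair 3 (3.90 ± 0.34) or pair 4 (4.21 ± 0.39). The blocked log2 fold changes of F25D1.5, E02C12.10, ugt-25 and ugt-33 were 2.73 ± 0.23, 1.90 ± 0.25, 1.505 ± 0.19 and 1.37 ± 0.16 (SE). F25D1.5 lost its call without pair 1 (log2 fold change 2.66 ± 0.33), E02C12.10 without pair 1, 2 or 4 (1.75 ± 0.32, 1.91 ± 0.26 and 2.39 ± 0.38), ugt-25 without pair 2 or 4 (1.46 ± 0.22 and 1.21 ± 0.23), and ugt-33 without pair 4 (1.496 ± 0.23), with highest adjusted p values of 0.284, 0.0988, 0.216 and 0.0885. F25D1.5 overlaps degt-1 and ugt-25 overlaps mlst-8, both on the opposite strand.

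**Figure D2:**
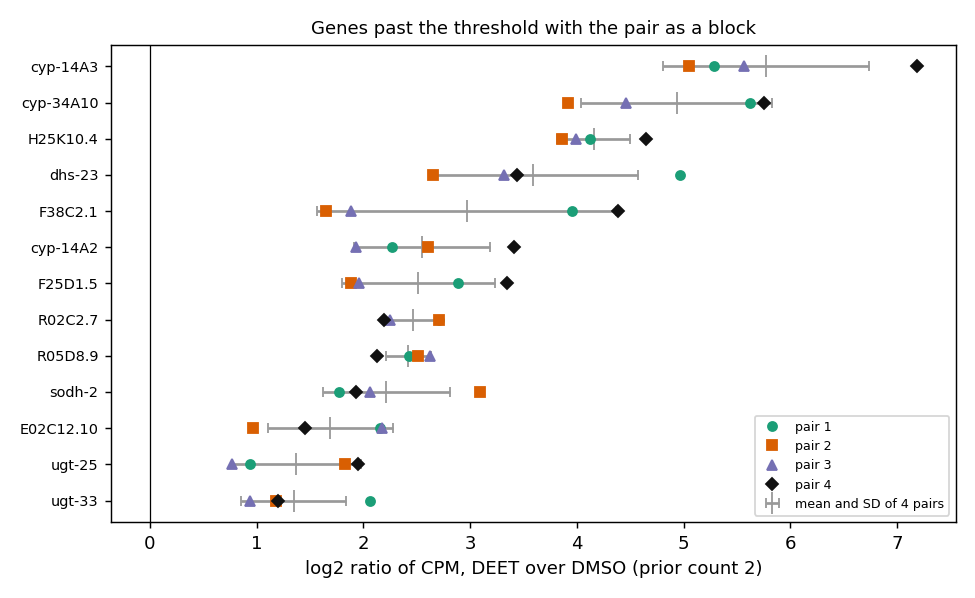
The log2 ratio of CPM, DEET over DMSO, in each of the 4 pairs for the 13 genes past the threshold in the blocked fit, with the mean and SD of the pairs. Every ratio lies above 0, from 0.77 for ugt-25 in pair 3 to 7.19 for cyp-14A3 in pair 4, and the prior count of 2 lowers the ratios of genes with few DMSO counts.

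Among 62 tested P450 genes, 3 were higher and 59 did not pass over all genes with the block, and 5 were higher and 1 lower when adjusted over the list alone. The additional ones were cyp-34A9, at 3.77 ± 3.77 TPM in DMSO and 10.5 ± 8.61 TPM in DEET, cyp-35A5, at 0.70 ± 0.19 and 2.95 ± 1.80 TPM (SD, n = 4), and cyp-13A5, with a blocked log2 fold change of -0.26 ± 0.05 (SE). Without the block, 0 P450 genes passed over all genes and 4 were higher adjusted over the list alone. P450 genes were over-represented among the 13, with 3 found where 0.052 were expected (Fisher's exact test, two-sided, p = 1.7e-05, adjusted p = 5.1e-05 over 3 lists, chosen after the calls were seen). The 3 lists all held called genes, and the test counts the neighbours cyp-14A2 and cyp-14A3 as independent, so its p is descriptive only.

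The camera test put the P450 list higher with the block (adjusted p = 2.6e-05), against 0.084 without the block and an adjusted p of 0.295 with an estimated correlation and the block. The list's mean log2 ratio was 0.24 ± 0.06 (SD of 4 pairs) and above 0 in 4 of 4 pairs. Its median blocked log2 fold change was -0.03, opposite in sign to the mean and the test, and of the 59 members not called, 26 lay above 0 and 33 below. The list's rise was that of a few members.

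Among 60 UDP-glucuronosyltransferase genes, 2 were higher over all genes with the block and 5 adjusted over the list alone, adding ugt-34, ugt-9 and ugt-66. Their blocked log2 fold changes were 1.06 ± 0.17, 0.66 ± 0.13 and 1.09 ± 0.22 (SE), the last with 3 of 4 pairs higher and 0.45 ± 0.39 (SE) without pair 4. The list as a whole did not pass with the block and all pairs (camera adjusted p = 0.102; mean log2 ratio 0.09 ± 0.05, SD of 4 pairs), but was past the threshold, higher, without pair 2 (0.0454) and without pair 3 (0.0425). With an estimated correlation and the block its adjusted p was 0.883 with all pairs, 0.784 without pair 2 and 0.586 without pair 3. Of 30 short-chain dehydrogenase genes, dhs-23 alone passed (camera adjusted p for the list 0.562 with the block, and 0.0444 without pair 1, or 0.819 without pair 1 and with an estimated correlation). No member passed among 40 glutathione S-transferase genes, with an adjusted p of 0.211 for the list, or 46 ABC transporter genes, with 0.644, over all genes or over the list alone.

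Germline genes shifted little, and the shift lay in pair 4. With the block, camera put 3 germline lists higher in DEET: 31 oocyte and eggshell genes (adjusted p = 0.0021), 39 germ granule and germline regulator genes (0.0021) and 63 meiotic chromosome genes (0.045). The oocyte list's mean log2 ratio was -0.02, -0.02 and -0.02 in pairs 1, 2 and 3 and 0.24 in pair 4, and the germ granule list's was -0.01, -0.01, -0.01 and 0.19. The meiotic list's mean was 0.02 ± 0.05 (SD of 4 pairs), with 0.10 in pair 4. No gene of the 3 lists passed the threshold, over all genes or over the list alone. None of the 3 lists passed without the block, with adjusted p values of 0.328, 0.273 and 0.357, or with the block and without pair 4; the meiotic list was also lost without pair 2. With an estimated correlation and the block the adjusted p was 0.883 for each.

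The lists of 40 DNA damage response and apoptosis genes and 47 small RNA pathway genes did not pass with the block (adjusted p = 0.077 and 0.168), and both had their highest ratio in pair 4, at 0.11 and 0.09. For 28 major sperm protein genes and 61 other sperm genes the ratio moved in opposite directions between pairs, from -0.28 in pair 2 to 0.29 in pair 3 and from -0.34 to 0.31, with adjusted p values of 0.466 and 0.211. The 6 vitellogenin genes, which encode yolk proteins, had a mean log2 ratio of -0.03 ± 0.03 (SD of 4 pairs; adjusted p = 0.245).

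**Figure D3:**
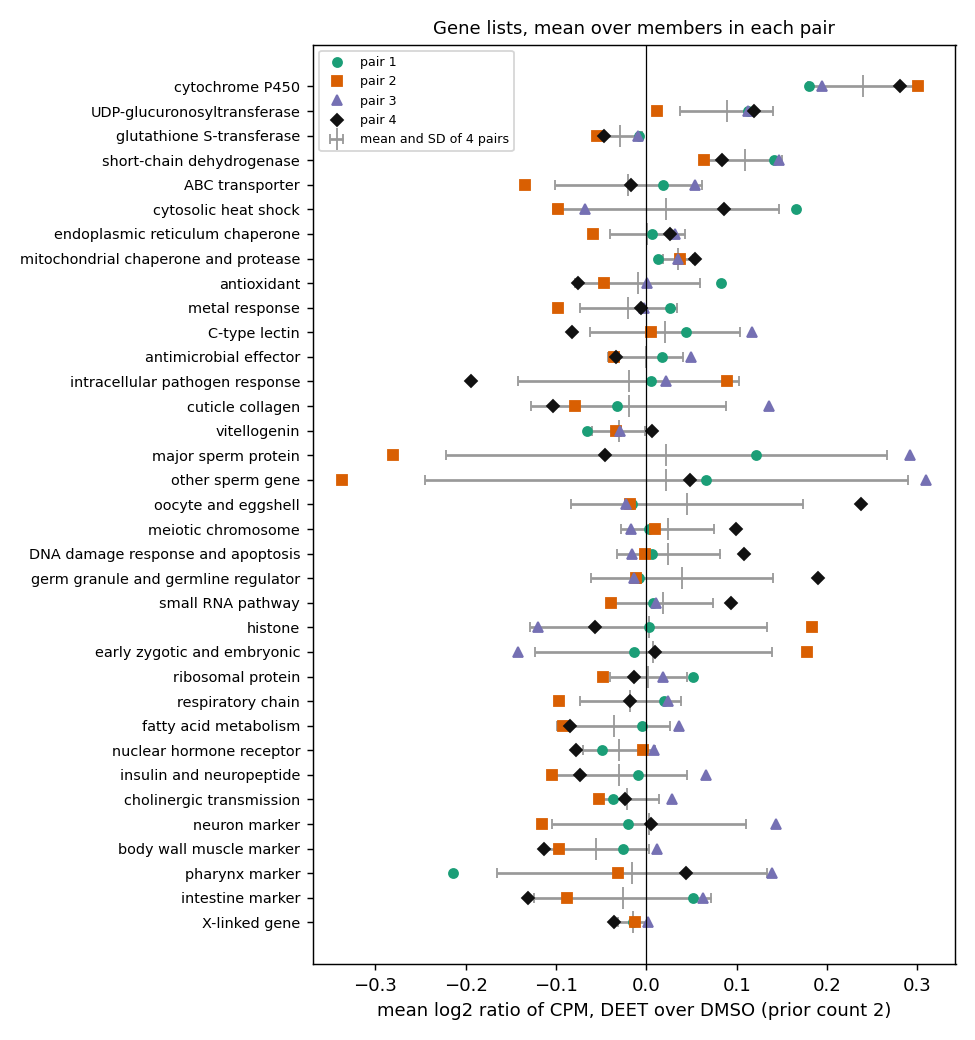
The mean log2 ratio of CPM, DEET over DMSO, over the tested members of each of 35 gene lists in each pair, with the mean and SD of the 4 pairs. The P450 list lies above 0 in all 4 pairs, at 0.18 to 0.30, while the oocyte and germ granule lists lie above 0 only in pair 4.

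Body wall muscle markers were lower with the block (27 genes, 21 of them below 0; camera adjusted p = 2.6e-05), against 0.084 without the block and 0.883 with an estimated correlation and the block. The shift was small, at -0.06 ± 0.06 (SD of 4 pairs), and negative in 3 of 4 pairs, at -0.03, -0.10, 0.01 and -0.11 in pairs 1 to 4. Intestine markers, at 0.05, -0.09, 0.06 and -0.13, were also lowest in pairs 2 and 4, and pair 4 is the one set apart on the first component and the one where the oocyte and germ granule lists were higher. The myosin gene unc-54 and the sarcomere gene unc-89 had blocked log2 fold changes of -0.15 ± 0.05 and -0.13 ± 0.05 (SE), and neither passed on its own. The 102 fatty acid metabolism genes were also lower with the block (adjusted p = 0.0018), against 0.126 without it and 0.883 with an estimated correlation and the block. Their mean was -0.04 ± 0.06 (SD of 4 pairs), and the list did not pass without pair 2 or pair 4. The acyl-CoA synthetase gene acs-2 and the lipase gene lipl-2 had blocked log2 fold changes of -0.26 ± 0.05 and -0.22 ± 0.05 (SE), with adjusted p values of 0.294 and 0.501. In other blocked edgeR fits acs-2 passed without pair 4 (adjusted p = 0.036) and without a filter (0.048), and lipl-2 passed in none.

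Without the block, 0 of 35 lists passed, with 5 at an unadjusted p under 0.05 and a smallest adjusted p of 0.084, and fry called 0 lists. The only other list with a member past the threshold over the list alone without the block was that of X-linked genes, through the P450 gene cyp-14A3. This count moved widely when single libraries were left out: it was 5, 9, 14 and 16 without DMSO 1, 2, 3 and 4, and 2, 6, 0 and 18 without DEET 1, 2, 3 and 4. With the block, 6 lists passed and 2 of them without pair 4, P450 genes and body wall muscle markers. With an estimated correlation and the block, 0 lists passed with all pairs or without pair 4, where the adjusted p was 0.981 for both. With DEET and DMSO exchanged within some pairs, the block at the preset correlation took 7 to 19 lists past the threshold, each time more than the real 6.

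Stress and immune lists did not pass with the block. The adjusted p was 0.400 for cytosolic heat shock genes, 0.893 for endoplasmic reticulum chaperones, 0.102 for mitochondrial chaperones and proteases, 0.730 for antioxidant genes and 0.106 for metal response genes. It was 0.594 for C-type lectins, 0.363 for antimicrobial effectors and 0.644 for intracellular pathogen response genes. Of the metal response genes, the metallothionein gene mtl-1 passed over the list alone, with a blocked log2 fold change of -0.18 ± 0.04 (SE) and lower levels in DEET in 4 of 4 pairs. For 140 cuticle collagen genes the adjusted p was 0.154, and col-17 and bli-1 were lower when adjusted over the list alone, with blocked log2 fold changes of -0.44 ± 0.07 and -0.44 ± 0.09 (SE). The gene that names the strain, col-121, was at 0.73 ± 0.34 TPM in DMSO and 0.75 ± 0.22 TPM in DEET (SD, n = 4).

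The other lists did not pass with the block either. Their adjusted p values were 0.910 for histones, 0.575 for early zygotic and embryonic genes, 0.730 for ribosomal proteins, 0.128 for respiratory chain genes, 0.077 for nuclear hormone receptors and 0.154 for insulin and neuropeptide genes. They were 0.575 for cholinergic transmission, 0.260 for neuron markers, 0.794 for pharynx markers, 0.106 for intestine markers and 0.100 for 2170 X-linked genes, of which cyp-14A2 and cyp-14A3 passed.

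Of the 29 lists that did not pass with the block and all pairs, 14 passed with 1 pair left out, none of them without pair 4. With an estimated correlation, 0 lists passed in these fits, and the smallest adjusted p was 0.417, 0.768, 0.370 and 0.981 without pairs 1, 2, 3 and 4. At the preset correlation, UDP-glucuronosyltransferase and cytosolic heat shock genes were higher without pair 2 or pair 3, as were small RNA pathway genes, other sperm genes were higher without pair 2, short-chain dehydrogenase genes without pair 1, and DNA damage response genes without pair 1 or pair 3. Nuclear hormone receptors were lower without pair 2 or pair 3, intestine markers without pair 1 or pair 3, histones and X-linked genes without pair 2, and cuticle collagen, insulin and neuropeptide, and neuron lists without pair 3. Major sperm protein genes were higher without pair 2 and lower without pair 3.

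DESeq2 with the block called all 13 genes above and 7 more. Higher in DEET were R09E12.9, with a DESeq2 log2 fold change of 5.50 ± 0.51 (SE; DESeq2 adjusted p = 6.4e-23, edgeR adjusted p with the block 0.105), cyp-34A9, gba-2, W01A11.1 and lin-65. R09E12.9 stood at 6.58 ± 10.3 TPM in DMSO and 185 ± 184 TPM in DEET (SD, n = 4), and its blocked edgeR log2 fold change of 4.99 ± 0.37 was 6.06 ± 0.25 (SE) without pair 4, where it passed (adjusted p = 0.0020). Lower were pud-1.2 and pud-2.2, abundant genes at 2027 ± 376 and 2586 ± 398 TPM in DMSO (SD, n = 4), with DESeq2 log2 fold changes of -0.22 ± 0.05 and -0.22 ± 0.05 (SE) and adjusted p values of 0.0040 and 0.0076. Both pud genes have near-identical copies in the genome, so their counts are uncertain as to copy, and gba-2 and W01A11.1 overlap gba-1 and moc-2 on the opposite strand. Without the block DESeq2 called 8 of the 13 genes, with R09E12.9 and cyp-35A5.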

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

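The tests in this part were chosen after the results they bear on were seen, except the counts of gene lists over other groupings of the libraries. For each named gene, gene list and library measure, the distance of the most extreme of 4 libraries from its nearest neighbour was divided by the range of its group. Of 140 such groups 28 lay above the 95% critical value, where chance alone gives about 1 in 20, or 7, and in 27 of the 28 the extreme library was of pair 4. The groups share libraries and are not independent. The critical value assumes normally distributed values, while the TPM of the named genes were not on a log scale. All of those genes but col-121 were also named after their values were seen. The 7 is therefore only a rough guide.

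In the DMSO group, library 4 was high for the mean levels of cytosolic heat shock (0.903 of the range), metal response (0.977), glutathione S-transferase (0.879), C-type lectin (0.862) and antimicrobial effector genes (0.836). It was low for oocyte and eggshell (0.901), germ granule (0.917) and small RNA pathway genes (0.930). It was also high for the TPM of dhs-23 (0.891), ugt-33 (0.920), col-17 (0.865), ugt-34 (0.942), R09E12.9 (0.990), ugt-66 (0.985) and lipl-2 (0.837). DMSO library 2 was low for W01A11.1 (0.938). In the DEET group, library 4 was low for oocyte and eggshell (0.866), germ granule (0.888) and small RNA pathway genes (0.841) and for lin-65 (0.887). It was high for intestine markers (0.875), the share of ribosomal RNA (0.924), and F38C2.1 (0.881), ugt-25 (0.836), col-17 (0.856), ugt-34 (0.917), ugt-9 (0.946) and ugt-66 (0.971).

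Pair 4 stood apart in both groups. A lower share of germline RNA as the whole difference is argued against, since it would raise all somatic lists alike, while the medians of 6 somatic lists ranged over 2.80 on the log2 scale in the DEET library and more in the DMSO library, with vitellogenin low and cuticle collagen high. Worms of an earlier stage in pair 4 may account for the pattern: cuticle collagen and major sperm protein lists were higher and vitellogenin and oocyte lists lower in both libraries, by at least 0.60. This hypothesis was drawn from the same values, the design names no biological difference between the pairs, and a handling or ribosomal RNA difference stays open. Without the block, the grouping of pairs 1 and 4 against pairs 2 and 3 called 2005 genes, the most of the 35 groupings, which shows a structure of the samples.

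The germline lists were higher with DEET in the blocked fit at the preset correlation, but did not pass camera with an estimated correlation (adjusted p = 0.883 for each). That form of the test passed no list in any fit, so it does not decide the question. A shift common to the pairs is argued against, since the mean log2 ratio over the 3 lists together was 0.16 in pair 4 and at most -0.0030 in the other pairs. A DMSO library of pair 4 further from the other pairs than its DEET library cannot be told apart from a DEET effect confined to pair 4. Across 15496 genes, the pair 4 ratio had a correlation of -0.19 with the distance of pair 4 from pairs 1 to 3. Pairs 1, 2 and 3, each taken against the rest, gave -0.09, 0.21 and -0.19, and genes are not independent. The correlation therefore does not decide the question. Of the 8 groupings of the libraries that keep the pairs, the real one took the fewest lists past the camera threshold, at 6. The others took 7 to 19. The number of lists passed with the block therefore does not set the treatment apart from arbitrary groupings. Without the block the real count was 0 lists, which all 35 groupings reach by definition, so that comparison says nothing about chance; the highest other count was 23.

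The 13 genes were higher with DEET in the blocked fit. Library scaling as their cause is argued against, since in counts with no scaling the log2 ratio over the 13 genes and 4 pairs was at least 0.74, while totals and scaling factors differed within a pair by at most 0.12. Reads moved between close copies are argued against as the whole cause of the rise in the cyp-14A family. The CPM summed over 5 cyp-14A genes rose in each pair by a log2 ratio of at least 0.69. Reads passed between cyp-14A2 and cyp-14A3 leave that sum unchanged, so it cannot show how the rise divides between them. For cyp-34A10 moved reads cannot be told apart from a rise. The sum over 6 cyp-34A genes had a log2 ratio of only 0.019 in pair 2, where cyp-34A8 dominates the sum. It reached 0.77 in pair 4. Of the 8 groupings that keep the pairs, 1, the real one, called as many as 13 genes and the highest other called 0, and 8 are too few for a share under 0.05; without the block the real count was 0, which all 35 groupings reach by definition (the highest other 2005), so that comparison says nothing about chance. The log2 ratios of single pairs were 5.05 to 7.19 for cyp-14A3, 3.86 to 4.65 for H25K10.4 and 2.19 to 2.71 for R02C2.7. These genes were called with any pair left out, in refits of the same data that are not independent support. The planned blocked test put them higher in the treated worms, while the main fit without the block passed none of them. Library scaling does not account for their rise. For H25K10.4 and R02C2.7 no other technical explanation was tested. For cyp-14A3, reads shared with cyp-14A2 stay open as part of its rise. A response to DEET is the biological hypothesis.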

How the results depend on the processing

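Apart from DESeq2 and the estimated correlation over all pairs, the fits that change a choice while keeping the block were chosen after seeing the data, as were those that leave out pair 4 or remove ribosomal RNA. The count of 0 genes without the block became 13 with the replicate block, 3 with DESeq2 size factors, 3 without a filter, 3 on log2(TPM + 0.1), 1 on log2(TPM + 1) without a filter, 10 with DESeq2, 20 with DESeq2 and the block, and 4 without pair 4. Leaving out 1 library gave 0 to 3. It stayed 0 with upper-quartile factors, a mean of at least 50 counts, log2(TPM + 1) and no ribosomal RNA genes; the stricter thresholds can only leave it at 0. With the block, the count of 13 became 30 without a filter (22 higher and 8 lower), 4 on log2(TPM + 1), 3 on log2(TPM + 0.1) and 20 with DESeq2; the other settings gave 10 to 16, with 1 lower without pair 1 and with limma-voom, 4 lower without pair 4 and 0 lower in the rest, and the 13 genes were higher in every fit that tested them. The cause of these moves was not tested.

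The count of 0 lists became 6 with the replicate block, 1 without a filter, 8 with a mean of at least 50 counts, and 1 without pair 4. Leaving out 1 library gave 0 to 18. With the replicate block it was 9, 12, 16 and 2 without pairs 1, 2, 3 and 4, and 8 without ribosomal RNA genes. It stayed 0 with other scaling, on TPM, with fry and with an estimated correlation, also with the block and 1 pair left out. Adjusted over a list alone, the block took the genes past the threshold from 4 to 5 higher and 0 to 1 lower for P450, from 0 to 5 higher for UDP-glucuronosyltransferase, from 0 to 1 higher for short-chain dehydrogenase and from 1 to 2 higher for X-linked genes, and from 0 to 1 lower for metal response and 0 to 2 lower for cuticle collagen genes. It changed no other call.

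Camera reversed the direction of some lists and took them past the threshold, with no separate test of the cause. Without DMSO replicate 4 these were the oocyte, germ granule, meiotic, DNA damage, small RNA, cuticle collagen, insulin and neuropeptide, antimicrobial, intracellular pathogen and intestine lists. Without DEET replicate 4 they were both sperm lists, and without DMSO replicate 2 the endoplasmic reticulum chaperones. These fits held no block, so the library left in pair 4 had no partner. In DEET library 4 the median cuticle collagen gene lay 1.78 above libraries 1 to 3 and the median oocyte gene at -0.60. Without DMSO replicate 4 these lists went up and down. The median major sperm protein gene lay 1.08 higher in DMSO library 4, and that list went down without DEET replicate 4. The reversals without 1 library of pair 4 therefore cannot be read as effects of DEET. Against their direction without the block, major sperm protein genes reversed in the blocked fit without pair 3 (adjusted p = 0.014) and histones in that without pair 2 (0.016). In the blocked fit of all pairs camera also gave histones a downward direction, but the list did not pass (adjusted p = 0.910). Its mean log2 ratio over the pairs was 0.002.

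Over the fits that leave out 1 library, the adjusted p ran from 3.52e-11 to 0.976 for oocyte, from 2.37e-09 to 0.921 for germ granule, from 6.86e-08 to 0.878 for meiotic, from 5.91e-07 to 0.878 for DNA damage and from 9.18e-07 to 0.990 for small RNA genes. It ran from 1.16e-09 to 0.557 for cuticle collagens, from 3.77e-06 to 0.991 for insulin and neuropeptide genes, from 0.00184 to 0.878 for antimicrobial effectors, from 0.0302 to 0.920 for intracellular pathogen genes and from 0.00867 to 0.991 for intestine markers. It ran from 9.17e-08 to 0.990 for major sperm protein genes, from 6.84e-09 to 0.998 for other sperm genes and from 0.00106 to 0.992 for endoplasmic reticulum chaperones. Low counts limit the fold changes of cyp-14A3, cyp-34A10, H25K10.4 and F38C2.1, whose DMSO libraries held 0 to 12 counts. Their SEs were 0.63, 0.41, 0.59 and 0.70 in DESeq2 with the block, against 0.24, 0.20, 0.26 and 0.43 in the blocked edgeR fit.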

Other observations

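Apart from the treatment, pair 4 differed from the other pairs in cuticle collagen, sperm, yolk and oocyte genes. Taking library 4 against the mean of libraries 1 to 3 of its group, the median cuticle collagen gene was higher by 1.96 in DMSO and 1.78 in DEET on the log2 scale, and the median major sperm protein gene by 1.08 and 0.95. The median vitellogenin gene lay at -1.08 and -1.02, the median oocyte and eggshell gene at -0.92 and -0.60, and the median germ granule gene at -0.74 and -0.50. Ribosomal protein genes, at -0.03 and -0.03, and respiratory chain genes, at 0.03 and 0.04, hardly moved. These are descriptions of single libraries, with no test.

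Cytosolic heat shock genes had a mean level of 6.30 log2 CPM in DMSO 4 against 5.07 to 5.19 in the other DMSO libraries. Their median difference was only 0.09, so a few members carried the mean.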
